A study of Arabidopsis thaliana with 12 samples.

How the data were processed

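Transcript levels in Arabidopsis thaliana (wild type, ecotype C24) were measured by array from total RNA. The 12 samples fall into 2 groups of 6, plants grown under light that favours photosystem II and plants grown under the same light and treated with DCMU. The labels number the samples 1 to 6 in each group. Labelling, scanning, background correction and the scaling method are not given in the sources used here.

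The deposited table holds 1 spot intensity per probe and sample, on a linear scale, for 3439 probes. The intensities had been scaled by the authors, as far as the values show: array totals differed by a factor of at most 1.03, no value was below 0, and 11 values of 2 probes stood at a ceiling of 100, so their true level may have been higher. Between 3.93% and 4.22% of the probes in each array were listed at exactly 0. No background, detection flag or second channel was used here, so a probe's level cannot be set against its local background, and the number of arrays limits the precision. All 12 columns were used.

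Probe names came from the platform annotation. Of the 3439 probes, 692 were annotated to 1 gene, 870 to several genes and 1877 to none in the table used here. Only probes with 1 gene were named. Symbols were updated through the gene identifier against the RefSeq TAIR10.1 gene table, in which 690 of the 692 were found; list members carry the symbol of the fixed list at the same locus. Probe sequences were not used, so no name was checked by sequence, and the probe of a multigene family may report several near-identical copies.

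The values were kept as the authors had scaled them, because totals lay within 10% of each other. Values under 0.0669, the 1st percentile of positive values, were set to that floor before taking log2. The 160 probes at or under the floor on every array were left out (101 of them were listed at 0 on all arrays), and spots of 1 gene were averaged, which left 3278 features, 651 of them with a gene name. None of the called features had a replicate at the floor.

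Before any test, the sample numbers were compared within each group. Deviations from the group mean correlated at 0.36 to 0.67 across features between numbers 1 and 2, 3 and 4, and 5 and 6, in both groups, and at -0.58 to -0.11 between all other numbers. Such deviations cancel out within a group by construction, so negative correlations here and across groups follow in part from the centring. By a rule set before the data were examined, each such pair was averaged on the log2 scale and counted as 1 replicate, which gives 3 replicates per group (numbers 1-2, 3-4 and 5-6). The labels do not say whether these came from separate plantings, so p-values measure the spread between these 3 replicates, which may be technical. The same check across groups gave correlations of 0.38, 0.44 and 0.41 between replicates of the same numbers and -0.38 to 0.01 between replicates of different numbers. All 3 were over 0.1, so the numbers were taken to pair the replicates across groups, and a fit with the replicate number as a block was run beside the fit without it. The fit without the block was the main one. It leaves the pairing out, and calls are from it unless stated.

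Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all 3278 features, threshold 0.05). In data simulated from the levels and spread of this comparison (3278 features, 200 of them changed), the test recovered 90 of 100 features changed by 1 on the log2 scale and 57 of 100 changed by 0.5, with 4 false calls. The simulated noise was independent between features and replicates. It held none of the deviations that the real replicates share, so the 4 false calls do not give the error rate of the real comparison. A total of 20 gene lists, 454 loci in all, were fixed before the data were examined; 9 lists had at least 1 named and measured member, 21 genes together, and 11 had none. The lists without a measured member were isoprenoid and carotenoid synthesis, electron transport and ATP synthase, plastid transcription, plastid proteases and chaperones, light stress proteins, protein import, starch metabolism, photorespiration, jasmonate synthesis, chlorophyll breakdown and senescence, and root plastid isoforms, the last pair standing for other tissue states. Lists with 5 or more measured members were tested with limma's camera (preset correlation 0.01), which left 1 list. Groups of replicates were set apart on the first 3 principal components with an exact permutation test, whose smallest possible p with 3 against 3 is 0.1.

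The genes named were, by rule, the 10 with the largest rise and the 10 with the largest fall among called named genes whose groups did not overlap, and the 2 members of each tested list with the smallest p. None of the 18 genes fixed for naming in advance had a probe of its own name. The other measured list members are also given, and 4 further called genes, and the called probes brighter than that of LHCB1.5, were added after their values were seen. Alternatives covered the scaling (array medians, quantile normalization), the floor, a filter on dim features, single spots, the variance model, array weights, the replicate block, all 12 samples as replicates, the threshold, an exact permutation test per feature, camera with an estimated correlation, fry, and leaving out each replicate. Added after seeing the data were a random block for the averaged samples, the replicate block after rescaling, pooled photosynthesis lists, and lists widened to probes annotated to several genes of which at least 1 is a list member. Figures were drawn with matplotlib 3.10.9. No coordinates are given because the sources used here name no genome build for the probes.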

Results

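Transcript levels were compared between Arabidopsis plants grown under light that favours photosystem II and plants grown under the same light and treated with DCMU. DCMU (diuron) is a herbicide that blocks electron flow from photosystem II to the plastoquinone pool. The comparison asks which transcripts differ between treated and untreated plants. No measure of electron flow was used here, so a difference cannot be assigned to that block alone. Each group held 6 arrays, which were averaged to 3 replicates. Array totals ran from 3643 to 3768 in the authors' scaled intensity units, and the median spot from 0.596 to 0.687. All levels below are in these units. Gene names are those of the platform annotation and were not checked by sequence.

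DCMU-treated plants differed from untreated plants in 167 of 3278 features, 104 lower and 63 higher. The falls were larger than the rises: 36 features fell at least 2-fold and 1 rose that much, with a largest fall of 6.24-fold (probe 750) and a largest rise of 2.36-fold (probe 2398), both of probes with no single gene name here. The median change was -0.79 on the log2 scale among features that fell and 0.61 among those that rose. Among the 651 features with a gene name, 14 fell and 10 rose, and with the replicate number as a block 28 fell and 72 rose. In the plot of fold change against level, the light-harvesting gene LHCB1.5 stands among the brightest probes that fell.

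**Figure D1:**
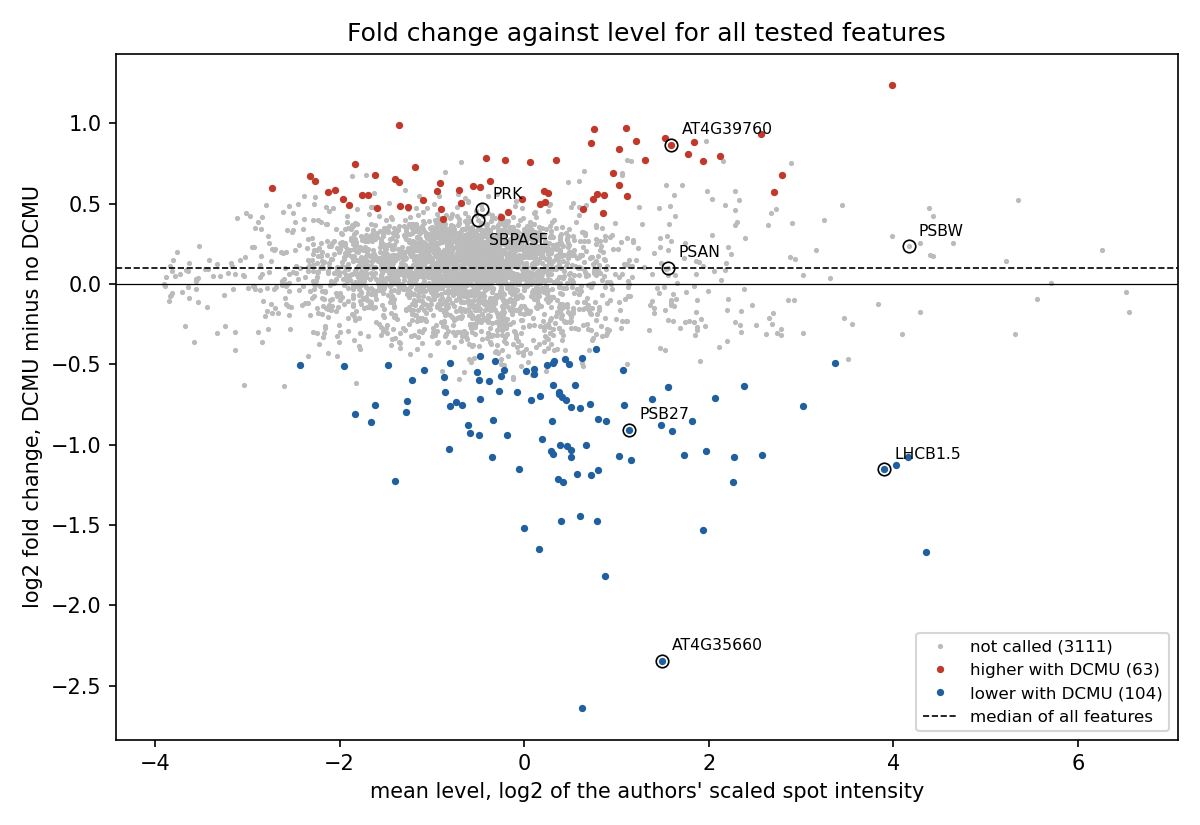
Each point is 1 of 3278 features; the x axis gives its mean level over 6 replicates (log2 of the authors' scaled spot intensity) and the y axis its log2 fold change, DCMU minus no DCMU (3 replicates each). Red points (63) rose and blue points (104) fell at an adjusted p under 0.05, grey points were not called, and the dashed line marks the median of all features, 0.10.

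These calls come from limma's moderated test with Benjamini-Hochberg adjustment (3 replicates per group), and 804 features had an unadjusted p under 0.05. With the replicate number as a block, 566 features passed, 351 higher and 215 lower, and these included all 167. The balance of the blocked fit turned after rescaling, to 175 higher and 326 lower after median centring and 185 higher and 280 lower after quantile normalization. The median feature was 0.10 higher on the log2 scale in DCMU-treated plants. After each array was centred on its median, the fit without the block called 150 lower and 56 higher. The count of 167 became 82 without untreated numbers 1-2, 77 without DCMU numbers 1-2, 282 without untreated numbers 3-4, 87 without untreated numbers 5-6 and 90 without DCMU numbers 5-6. The first principal component held 51.9% of the variance and separated all 3 treated replicates (8.17 ± 1.13, SD, n = 3) from the untreated ones (-8.17 ± 4.85, SD, n = 3). The exact permutation test gave p = 0.1 for it, the smallest that 3 against 3 allows, and adjusted p = 0.3 over 3 components. The same permutation test gave p = 0.6 for the second and p = 1 for the third component.

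Of the 4 measured members of the photosystem II list, 2 fell with DCMU and 2 did not pass the test. LHCB1.5 (AT2G34420), a chlorophyll a/b-binding protein of the main light-harvesting antenna, fell 2.22-fold, from 22.3 ± 2.85 to 10.02 ± 1.25 (SD, n = 3; limma, adjusted p = 0.000912). PSB27 (AT1G03600), a lumenal protein of photosystem II assembly and repair, fell 1.88-fold, from 3.03 ± 0.378 to 1.62 ± 0.250 (SD, n = 3; limma, adjusted p = 0.00410). Adjusted over the list alone, the same 2 of 4 members passed. This adds no support, because both had already passed the adjustment over all features. PSBW, a small subunit of the photosystem II core, had a log2 change of 0.23 (95% interval -0.04 to 0.51), and PSBY, another small subunit, one of -0.30 (-0.62 to 0.02). With the replicate block after quantile normalization PSBW had limma's adjusted p = 0.0193, and over all alternatives the adjusted p was 0.0193 to 0.531 for PSBW and 0.0415 to 0.505 for PSBY. The low end for PSBY came from taking all 12 samples as separate replicates. LHCB1.5 belongs to a family of near-identical copies, which its probe may not separate.

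Photosystem I and the Calvin cycle had few measured members, and none passed the test. PSAN, a photosystem I subunit, was at 2.85 ± 0.119 without and 3.06 ± 0.131 with DCMU (SD, n = 3), a log2 change of 0.10 (95% interval -0.12 to 0.32). Both measured Calvin cycle enzymes had positive changes: phosphoribulokinase (PRK) 0.46 (0.11 to 0.82) and sedoheptulose bisphosphatase (SBPASE) 0.40 (0.11 to 0.69), with limma's adjusted p = 0.121 and adjusted p = 0.111. Adjusted over the list alone, 2 of 2 passed (limma, adjusted p = 0.0150 for both). That adjusts for these 2 genes only and not across the lists. With the replicate block their adjusted p was 0.0326 and 0.0279, and with the block after median centring it was 0.115 and 0.0606. The range of limma's adjusted p over all alternatives was 0.00907 to 0.246 for PRK and 0.00408 to 0.294 for SBPASE. Both low ends came from taking all 12 samples as separate replicates, which counts the paired numbers singly.

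All 5 measured plastid ribosomal proteins had negative log2 changes, but none of them passed the test alone, over all features or adjusted over the list alone. The members with the smallest p were RPL5, at -0.16 (95% interval -0.39 to 0.07), and RPS6, at -0.21 (-0.53 to 0.10); RPS10 was at -0.15, RPL17 at -0.06 and RPL34 at -0.04. Against a median of 0.10 over the other features, limma's camera placed the list lower (mean -0.12, adjusted p = 0.0451). That call is lost with an estimated correlation between genes (adjusted p = 0.110). With fry in place of camera the list had adjusted p = 0.0164, and fry's mixed test, open to both directions, gave adjusted p = 0.265. Because only 1 list was tested, each adjusted p of this list equals its unadjusted p. Without untreated numbers 3-4 or 5-6, or without DCMU numbers 1-2 or 5-6, the adjusted p was 0.109, 0.0814, 0.0558 or 0.0666, and over all alternatives of camera that kept the 5 members it ran from 0.0169 to 0.110. With all 12 samples as replicates RPL5 passed (limma, adjusted p = 0.0479, and 0.0479 to 0.577 over all alternatives).

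The remaining 5 lists with a measured member gave no call over all features. APS4, an ATP sulfurylase of sulfate assimilation, had a log2 change of 0.36 (95% interval 0.12 to 0.60; limma, adjusted p = 0.0892, 0.0337 with the replicate block, 0.0632 with the block after median centring, 0.0742 with it after quantile normalization, 0.0743 with the random block, and 0.00231 to 0.248 over all alternatives). It was the single measured member of its list and passed when adjusted over the list alone. In amino acid synthesis DHAD (branched-chain) was at 0.25, CBL (methionine) at 0.17 and AHAIR (branched-chain) at 0.09, and 0 of 3 passed over the list alone. DHAD passed with all 12 samples as replicates (limma, adjusted p = 0.00709, and 0.00709 to 0.397 over all alternatives). In the antioxidant and thioredoxin list PRXIIE was at 0.14, NTRC at 0.07 and FTRB at -0.06, again with 0 of 3. The chlorophyll synthesis enzyme CHLM was at 0.13 and the acyl-ACP thioesterase FATB at -0.09.

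The other 8 of the 10 largest falls among named genes lay outside the lists. AT4G35660 fell 5.08-fold, from 6.37 ± 0.864 to 1.25 ± 0.0977 (SD, n = 3; limma, adjusted p = 5.69e-06). AT4G18180, of the pectin lyase-like family, fell 3.14-fold, from 1.99 ± 0.246 to 0.631 ± 0.0495 (SD, n = 3; limma, adjusted p = 7.80e-05). AT3G04210, of the TIR-NBS family of disease resistance proteins, fell 2.28-fold, and AT2G36480 fell 2.22-fold. AT5G11550 fell 2.11-fold and AT3G50130 fell 1.92-fold. AT4G03150 fell 1.76-fold and the histidine synthesis enzyme AT-HF (HISN4) fell 1.66-fold. Of the 10 largest falls, 8 passed in every fit that left out 1 replicate; the exceptions were AT2G36480, which lost its call in 5 of 6 such fits, with limma's adjusted p = 0.104 without untreated numbers 1-2, and AT4G03150, with 0.0655 without DCMU numbers 1-2. AT2G36480 also did not pass with the intensity trend (limma, adjusted p = 0.0564). With a floor at the 10th percentile of positive values AT4G03150 was at -0.46, against -0.81 (limma, adjusted p = 0.0951). In the fit with the replicate block and all replicates, AT2G36480 and AT4G03150 had limma's adjusted p = 8.74e-06 and 0.000215.

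**Figure D2:**
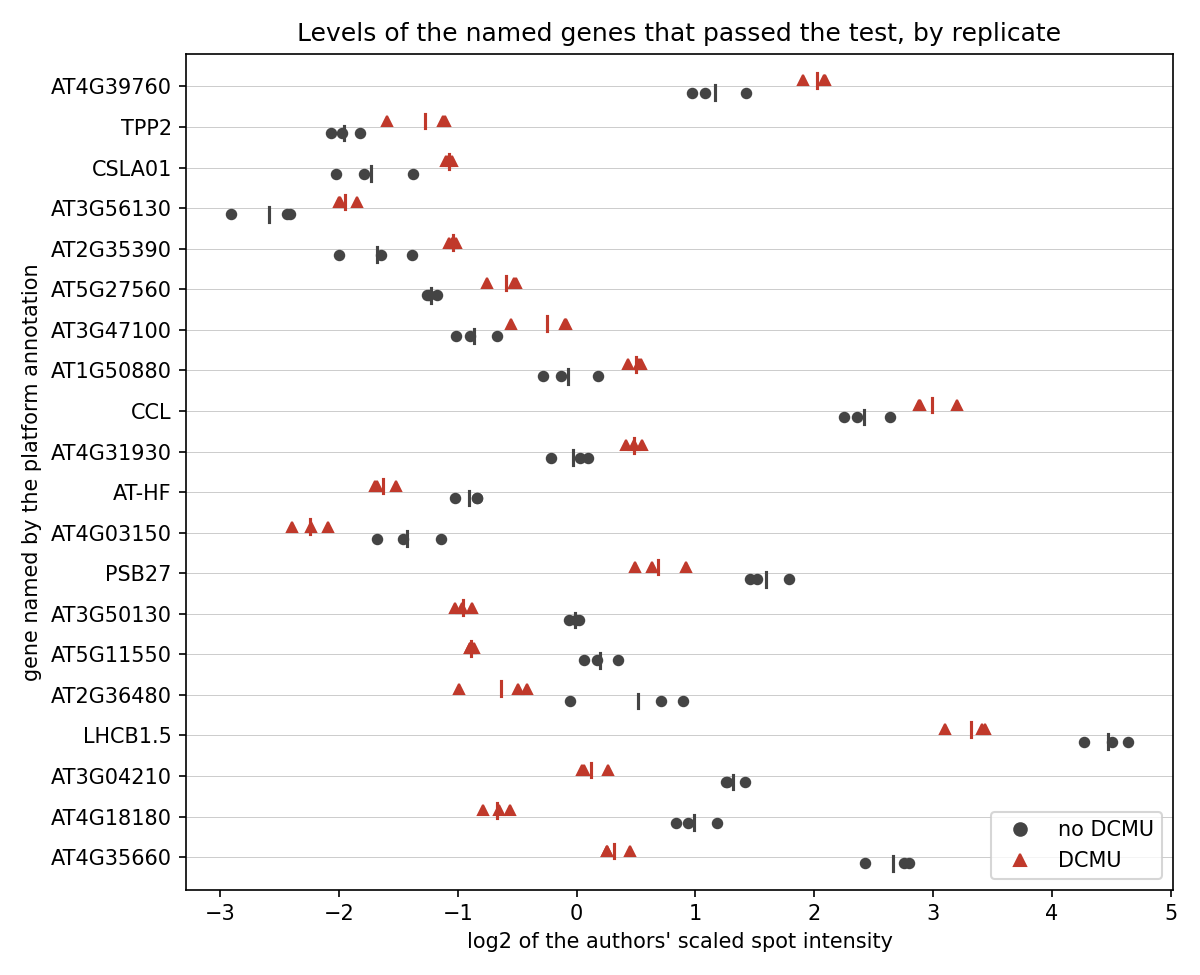
Levels of the 10 named genes with the largest rises and the 10 with the largest falls; the x axis is log2 of the authors' scaled spot intensity, each circle (no DCMU) or triangle (DCMU) is 1 of 3 replicates, and vertical bars are group means. Treated and untreated replicates do not overlap for any of these genes, a condition of the naming rule, and AT4G35660 shows the largest separation, 5.08-fold.

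The rises among named genes were smaller. AT4G39760, an F-box kelch-repeat protein, rose 1.82-fold, from 2.26 ± 0.383 to 4.08 ± 0.288 (SD, n = 3; limma, adjusted p = 0.00410). TPP2, the protease tripeptidyl peptidase II, rose 1.60-fold, and CSLA01, a cellulose synthase-like protein, rose 1.57-fold. AT3G56130 rose 1.56-fold and AT2G35390, a ribose-phosphate diphosphokinase, rose 1.55-fold. AT5G27560 rose 1.54-fold, AT3G47100 rose 1.53-fold and AT1G50880 rose 1.49-fold. CCL, named for its likeness to a circadian-controlled transcript, rose 1.49-fold, from 5.37 ± 0.760 to 7.98 ± 1.04 (SD, n = 3; limma, adjusted p = 0.0390), and AT4G31930 rose 1.43-fold. Only AT4G39760 passed in every fit that left out 1 replicate (highest adjusted p, limma, 0.0325). The other 9 each lost their call in 1 to 5 of 6 such fits, with a highest adjusted p between 0.0528 for AT5G27560 and 0.178 for AT3G47100. Those fits had no block, fewer replicates and 1 replicate without its partner in the other group. With the replicate block and all replicates, the 10 rises had limma's adjusted p between 0.000282 for AT4G39760 and 0.00696 for CCL. With the floor at the 10th percentile, 0.270, 4 of the rises did not pass. AT3G56130, whose replicates lay between 0.133 and 0.277, was then at a log2 change of 0.01 (limma, adjusted p = 0.922), TPP2 and CCL had adjusted p = 0.0524 and AT3G47100 had adjusted p = 0.0622. CCL also did not pass with the intensity trend (adjusted p = 0.0847), AT3G56130 with the random block (adjusted p = 0.0849), nor AT3G47100 after median centring or quantile normalization (adjusted p = 0.0717 and 0.0743).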

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

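With the replicate block 566 features passed (351 higher, 215 lower); with the block after median centring 501 (175 higher, 326 lower) and after quantile normalization 465 (185 higher, 280 lower). Among the genes and lists named, the block without rescaling changed the calls of PRK, SBPASE and APS4 and no other call. The fits with the block after rescaling and the fit of 12 samples with a random block were chosen after seeing the data; the random block gave 302 (166 higher). Array weights gave 359 (205 higher). All 12 samples taken as separate replicates gave 1089 (767 higher, 322 lower) and an exact permutation p = 0.00216 for the first component, with 6 against 6 samples in place of 3 against 3 replicates. Both treat the 12 samples as independent. Deviations correlated at 0.36 to 0.67 within paired numbers, so that assumption does not hold. The -0.58 to -0.11 between other numbers follows in part from centring on the group mean. The labels do not say what the paired numbers are. A false discovery rate of 0.1 gave 310 (167 higher). The exact permutation test per feature gave 0, since its smallest p of 0.1 cannot pass after adjustment; 1002 features (30.6%) had groups that did not overlap, where chance gives 10% for exchangeable replicates; the pairing of the numbers changes that share. The other planned settings gave between 150 and 206 features. Leaving out 1 replicate gave 77 to 282 features, 19 to 159 higher and 58 to 123 lower. The ribosomal protein list lost its call with array weights (adjusted p = 0.103) and with an estimated correlation (adjusted p = 0.110), and leaving out 1 replicate gave adjusted p = 0.0185 to 0.109. Without the dimmest features only RPL5 and RPL17 of its 5 members were left, too few for the list test (adjusted p = 0.234). Of the 24 called named genes, 17 kept their call in every planned limma fit with all replicates in which they were tested; the filter on dim features removed some of them. Among the genes named, signs turned only in ones that were not called. NTRC was at -0.00647 after median centring (also with the block) and at -0.00552 with array weights, AHAIR at -0.00096 after quantile normalization (also with the block). Without 1 replicate, NTRC was at -0.11 to 0.22, FTRB at -0.0977 to 0.00481, RPL34 at -0.0975 to 0.0346, RPL17 at -0.19 to 0.0104 and CHLM at -0.00703 to 0.24. Except where stated, the cause was not tested. Dim probes limit the rest: without background values, a level near the floor of 0.0669 cannot be told from none.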

Other observations

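The tests of the probe names and of the pooled and widened lists were chosen after the results were seen. Among the called named genes outside the naming rule, chosen after their values were seen, AT2G39100 fell 1.59-fold, the pseudouridine synthase family gene AT4G21770 fell 1.49-fold, the mTERF family gene AT3G18870 fell 1.41-fold and AT1G44830, of the ERF transcription factor family, fell 1.38-fold (limma, adjusted p = 0.0136, 0.0286, 0.0430 and 0.0478). Each lost its call in 2 to 5 of the 6 fits that left out 1 replicate. AT1G44830 also did not pass after quantile normalization (limma, adjusted p = 0.0532) or without a floor (adjusted p = 0.0521). Brighter than LHCB1.5 were 4 called probes without a gene name here, also singled out after their values were seen. Of these, probe 2881 fell 3.17-fold (limma, adjusted p = 0.00116), probe 2677 fell 2.18-fold (adjusted p = 0.00109) and probe 2689 fell 2.11-fold (adjusted p = 0.00139), while probe 2398 rose 2.36-fold, the largest rise among called features (adjusted p = 0.0136). When list membership was widened to probes annotated to several genes, the photosystem II list had 5 probes, of which 2 fell, with a mean log2 change of -0.48 (camera, adjusted p = 0.000838, and adjusted p = 0.120 with an estimated correlation). The 2 that fell are LHCB1.5 and PSB27, each already called alone, while PSBW had a log2 change of 0.23. The p of this list is therefore no separate support for a fall across its members. The Calvin cycle list, widened in the same way, had 4 probes, of which 1, annotated to several genes, rose. The antioxidant and thioredoxin list then had 7 probes and no call (camera, adjusted p = 0.677). The 7 named photosynthesis genes pooled gave camera's adjusted p = 0.236, with a mean of -0.17 and a median of 0.10, which differ in sign. With fry the pool had adjusted p = 0.0668, and fry's mixed test, open to both directions, gave adjusted p = 0.000628. The pool holds LHCB1.5 and PSB27, each already called alone, so the mixed result is no separate support.

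The balance of rises and falls moved with the scaling: with the replicate block 62.0% of calls were rises, and 34.9% after median centring, which lowers the changes of all features alike and so does not test where the shift comes from. Called falls of 2-fold or more numbered 36 against 1 such rise as scaled, 40 against 1 after median centring and 37 against 1 after quantile normalization. Whether the shift is technical or follows the treatment was not tested.

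Calls gathered among bright features: 69 of the 410 features in the brightest eighth were called (16.8%), against 98 of the other 2868 (3.42%). These counts come from the main fit, whose variance model has no intensity trend. They were not repeated with the trend, so how far the gathering depends on the variance model was not tested. A smaller replicate spread of bright features does not explain this, as their median replicate SD was 1.26 times that of the rest (95% bootstrap interval 1.17 to 1.33). Their median absolute change, centred on the median of all features, was 1.90 times that of the rest (1.59 to 2.11). A larger spread by itself also raises absolute changes, so this ratio cannot be read as an effect of DCMU alone. Both intervals come from resampling features as if independent and do not measure the spread between replicates. A background left in the values, which would shrink the folds of dim probes, was not tested and stays open.

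Whether the probe names are right stays open. Across 224 pairs of probes that share an annotated gene, log2 fold changes had a Spearman correlation of 0.00337 (one-sided permutation p = 0.481, 10000 permuted pairings). This neither bears out the names nor excludes them, because most features changed little and many of these probes are annotated to several genes. Probe pairs are not independent replicates.

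Of the 10 splits of the 6 replicates into 3 and 3, 1, the real one, gave 167 called features, and the highest of the others gave 0, including the 3 other splits that part all 3 pairs. With 10 splits a share under 0.05 cannot be reached. Every other split also mixes treated and untreated replicates in both groups. A treatment difference then adds to the spread within groups and lowers the count, so the 0 is no measure of calls without a treatment difference.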
